A study of Mus musculus with 7 samples.

How the data were processed

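RNA was measured by sequencing in 7 liver libraries: 3 from male mice lacking Mdr2 (KO), 3 from male wild-type (WT) mice and 1 from a female WT mouse. Per the labels' protocols, total RNA came from biopsies of the caudate lobe of BALB/cJ mice at 45 days of age, after a high-fat breeder chow fed from day 30 to day 45, and libraries were made with a TruSeq RNA kit. The labels do not say that each library came from a different mouse, so p-values measure only the spread between these samples, which may be technical.

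The deposited files hold 1 table of gene FPKM values (fragments normalized to transcript length and to the fragments mapped) per library with a status for each estimate, per the file headers. Per the submitters' processing notes, the tools named were Bowtie2, Cufflinks and DESeq, and the build was mm10; versions, settings and the gene annotation were not given in the sources used here. Each file had 32697 entries that could be read. A further 24 lines with shifted columns were not used, and 1 emptied line per file was not analysed here. FPKM is a normalized unit, and no whole-read step could be recovered from it: among low values, the most common ratio between a pair of libraries was shared by 4 to 8 of 1663 to 2380 entries. The depth of each library is therefore unknown, no counting interval could be given, and no count model was used. The sum of FPKM per library ran from 657970 to 797938, and the 50 genes with the highest values held 41.3% to 50.6% of it, so that a change in a few abundant genes can move every other value of a library.

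Entries with the status HIDATA were deposited at 0; they included albumin in 2 libraries and 15 entries of major urinary protein (Mup) genes in 5. Such a 0 is a failed estimate and need not mark a low level: albumin had 16008 to 24634 FPKM in the libraries with an estimate. Each such 0 was treated as missing, a choice made after the files were seen. The values as deposited were run as an alternative. There were 22, 21 and 24 such entries in the male WT libraries, 20, 1 and 0 in the male KO libraries and 22 in the female library. The status FAIL, found for 0 to 2 entries per library, was kept. Entries with the same symbol were summed. Starts are counted from 0 in the files and are given here counted from 1; 99.7% of 20864 symbols with a single entry overlapped the gene of that name in GENCODE M21 on GRCm38, the assembly that mm10 names. Near-identical genes, such as the Mup and Cyp2c families, share reads, and no source used here says whether strand was counted, so values of paralogs and of overlapping genes are uncertain.

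The names of the deposited files give 3 sequencing runs. The first held the female WT library with male KO 1 and 2, the second male WT 1 and 2, and the third male KO 3 with male WT 3. Only the third run held both male genotypes, so changes were also read within it.

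Tests were made on log2(FPKM + 1) without rescaling between libraries. A fold change on this scale understates the change of genes with low FPKM. Male KO was compared with male WT by limma 3.58.1 in R 4.3.3 (linear model, moderated variances with a mean trend, two-sided), over genes with FPKM of at least 1 in at least 3 of the 6 male libraries and at least 2 values per group, with Benjamini-Hochberg adjustment and a threshold of 0.05. The female library was set against male WT in 1 fit of 3 groups over all 7 libraries, in which the lone female library is assumed to vary like the male groups. The 42 gene lists, the groups, the tests and most alternatives were fixed before the data were examined. Lists with at least 3 tested genes, 36 in all, were tested by camera with its preset correlation of 0.01, which asks whether a list moved relative to the other genes. They were tested again by camera with an estimated correlation and by fry, which asks whether the genes of a list moved one way on balance. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots made with matplotlib 3.10.9.

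The genes named were set by rule: Abcb4, Slc10a2, Cyp7a1, Krt19 and Col1a1; the 10 largest rises and 10 largest falls among genes that passed, did not overlap between the groups and had a mean FPKM of at least 5 in the higher group, leaving out symbols of Gm followed by digits, those ending in Rik, those starting with LOC, Mir or Snor, and entries with several symbols; up to 4 members of each list with the smallest adjusted p; and, for the female library, the X-inactivation and Y-linked genes and the 4 members of each sex-biased list with the largest difference. Where 5 or fewer members of a list rose or fell, those outside the rule are also named, as are list members singled out in the text; these were chosen after their values were seen. A few genes that the rule or a count would name are not reported here.

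Alternatives were pseudocounts of 0.1 and 3, no filter, a filter at FPKM 5, median-of-ratios scaling, quantile normalization, rescaling without the 50 most abundant genes, no variance trend, library weights, the highest entry of a symbol, entries of doubtful status left out, replicate number or sequencing run as a covariate, the female library in the fit or pooled with male WT, and each library left out in turn. With a library left out the filter still asked for 3 libraries, so genes near 0 in male WT were not tested without a KO library. With run as a covariate, the difference between male KO and male WT comes from male KO 3 and WT 3 alone. A call lost in that fit therefore does not show that run explains the change. The procedure was tested on simulated data drawn from the spread of these libraries for 10698 genes. For male KO against male WT, it recovered 67 of 100 genes changed by 1 on the log2 scale and 96 of 100 changed by 2, with 7 false calls. For the female library it recovered 24 and 84 of 100, with 5 false calls. In 20 simulations without change camera called no list, and it called the 1 list that was raised and no other; genes were drawn independently there, which does not test camera on correlated genes.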

Results

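Gene expression was measured in biopsies of the caudate liver lobe from BALB/cJ mice aged 45 days that had eaten a high-fat breeder chow for 2 weeks. The mice either carried or lacked Mdr2, the product of the gene Abcb4, which moves phosphatidylcholine across the canalicular membrane of hepatocytes into bile. There were 3 libraries from male knockout (KO) mice, 3 from male wild-type (WT) mice and 1 from a female WT mouse. Between 9447 (female WT) and 11306 (male KO 3) entries reached 1 FPKM in a library, and the 3 male KO libraries had more than any WT library. Across 10698 genes, Pearson correlations of log2(FPKM + 1) were 0.985 to 0.987 between male WT libraries, 0.968 to 0.985 between male KO libraries and 0.908 to 0.936 between the genotypes. The first principal component held 66.1% of the variance and parted KO from WT, with male KO 3 farthest from the WT libraries. The depth of the libraries is unknown.

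The first comparison asked what the loss of Mdr2 changed in the male liver, and the targeted gene was read first. Abcb4, on chromosome 5 from 8893721 to 8959226 (mm10, plus strand, protein coding), had 50.3 ± 6.03 FPKM (SD, n = 3) in male WT and 3.94 ± 0.237 (SD, n = 3) in male KO. The KO libraries kept 7.97%, 7.29% and 8.20% of the male WT mean, and the female WT library had 54.7 FPKM. The change was −3.37 on the log2(FPKM + 1) scale (SE 0.16, limma adjusted p = 1.83e-07). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Abcb4 was thus low in each library labelled KO and high in each labelled WT.

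Slc10a2, which encodes the sodium-dependent bile acid transporter ASBT named in the title of the series, rose from 2.53 ± 0.765 to 12.6 ± 4.08 FPKM (chromosome 8, 5085623 to 5105232; log2 change 1.93, SE 0.25, limma adjusted p = 1.92e-04). Col1a1, the alpha chain of type I collagen, rose from 2.45 ± 1.13 to 50.2 ± 20.6 FPKM (chromosome 11, 94936270 to 94951856; 3.86, SE 0.31, adjusted p = 1.01e-05). Krt19, a keratin of bile duct cells, rose from 2.38 ± 0.731 to 7.91 ± 2.35 FPKM (chromosome 11, 100140811 to 100145919; 1.39, SE 0.24, adjusted p = 0.00132). Cyp7a1, the rate-limiting enzyme of bile acid synthesis (chromosome 4, 6265612 to 6275631), had 14.7 ± 9.26 FPKM in male WT and 21.8 ± 4.93 in male KO and did not pass (0.68, SE 0.35, adjusted p = 0.181). Without male WT 2, the highest of the male WT libraries, the log2 difference of Cyp7a1 was 1.13 and the adjusted p = 0.0124. The female WT library had 59.4 FPKM of Cyp7a1.

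**Figure D1:**
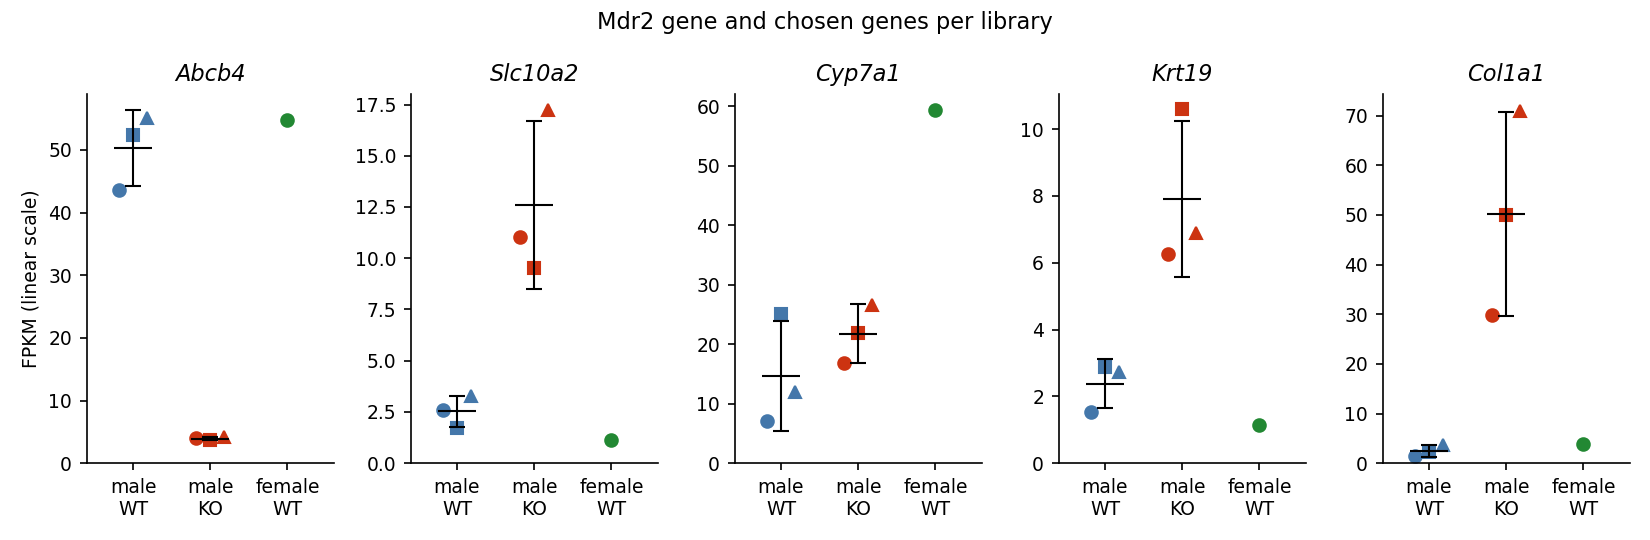
FPKM (linear axes from 0) of Abcb4, Slc10a2, Cyp7a1, Krt19 and Col1a1 in each library, with the mean and SD of the 3 male WT and 3 male KO libraries and the single female WT library. Circles, squares and triangles stand for replicates 1, 2 and 3; Abcb4 lies between 3.67 and 4.13 FPKM in KO and between 43.6 and 55.1 in WT, and Cyp7a1 overlaps between the male groups.

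A large part of the measured genes differed between male KO and male WT. The largest rise was that of Ly6d, a surface protein of the lymphocyte antigen 6 family (chromosome 15, 74762056 to 74763567), from 0.421 ± 0.394 to 950 ± 134 FPKM (SD, n = 3 each; log2 change 9.42, SE 0.21, adjusted p = 1.34e-09). The largest fall was that of Hsd3b5, a hydroxysteroid dehydrogenase of the male mouse liver (chromosome 3, 98618636 to 98645534), from 275 ± 30.2 to 0.470 ± 0.0624 FPKM (−7.55, SE 0.15, adjusted p = 6.55e-10). Of 10652 genes tested with limma, 3181 passed, 2706 of them higher and 475 lower in KO, and 1181 and 185 of these by at least 1 on the log2 scale. In 3863 genes all KO libraries lay above all WT libraries and in 764 below, together 43.4% of genes against 10% by chance. These were counted without rescaling only. The median level of all genes was itself higher in each KO library (lowest 0.023, male KO 1) than in each male WT library (highest −0.042, male WT 3). The 10% does not allow for such a shared shift.

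Other large rises were those of Lcn2, the iron-carrier-binding lipocalin 2 (10.3 to 1502 FPKM, log2 change 7.07), Cib3, a calcium-binding protein (0.899 to 239, 6.96), Sprr1a, a small proline-rich protein of stressed epithelia (0.0876 to 142, 6.84), and Ifi27l2b, of an interferon-inducible family (5.96). Ubd, a ubiquitin-like protein induced by inflammatory cytokines, rose from 0.187 to 64.0 FPKM (5.71). Scd1, the stearoyl-CoA desaturase, rose from 17.1 to 742 (5.36) and Gipc2, a PDZ-domain protein, from 0.120 to 31.1 (4.83). The entries AK219146 (5.68) and D17H6S56E-5 (5.10) also rose, but they lie over Grina and Vars and their reads cannot be told apart. AK219146 had 0.013, 0.001 and 46.1 FPKM in the male WT libraries and 201 in the female WT library, and its call was lost when that library was pooled with male WT (adjusted p = 0.074).

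Large falls after that of Hsd3b5 included those of Elovl3, a fatty acid elongase (563 to 5.68 FPKM, −6.78), Slco1a1, an organic anion uptake transporter (76.6 to 0.122, −6.09), Sult5a1, a sulfotransferase (76.1 to 0.134, −6.08), and Cyp7b1, an oxysterol hydroxylase of the alternative bile acid pathway (260 to 10.5, −4.55). The urinary pheromone carriers Mup21 (744 to 7.51 FPKM, −6.82), Mup3 (12180 to 644, −5.11) and Mup5 (160 to 9.07, −4.80) fell as well, as did Obp2a, an odorant-binding protein (23.1 to 0.203, −4.08), and the pseudogene Serpina4-ps1 (−4.50). Mup genes are near-identical and share reads, and Mup21 overlaps Mup3, Hsd3b5 overlaps Zfp697 and Elovl3 overlaps Pitx3 in the files, so their single values are uncertain.

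The values are shares of a library, and the median over all genes tested was itself shifted, by 0.23 on the log2 scale. Rescaling without the 50 most abundant genes moved that median to 0.06 and gave 1844 genes higher and 809 lower. Median-of-ratios scaling moved it to −0.06 with 1697 higher and 1435 lower. It moved to −0.09 under quantile normalization, with 1785 higher and 1993 lower. The share of higher genes was thus 85.1% as deposited, 69.5%, 54.2% and 47.2%. List medians given below as relative to, or above, all genes have this shift taken off, and the others are as fitted. Leaving out male KO 2 reduced the number of genes called to 1853.

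**Figure D2:**
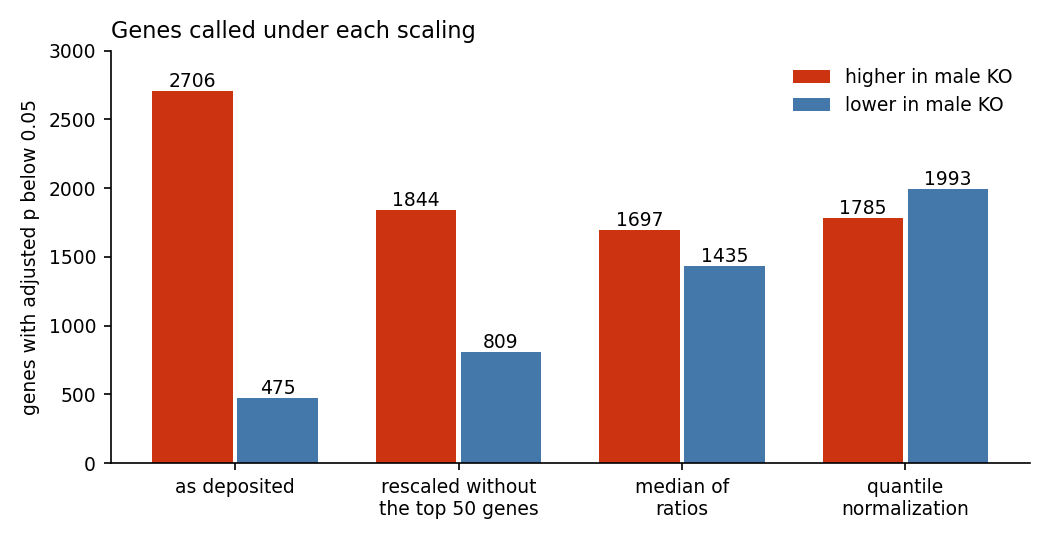
Number of genes with an adjusted p under the threshold (vertical axis, from 0) that were higher (red) or lower (blue) in male KO than in male WT, for the deposited FPKM and for 3 rescalings. Higher genes outnumber lower ones 2706 to 475 as deposited, while quantile normalization gives 1785 and 1993.

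Only the run of male KO 3 and male WT 3 held both male genotypes. In that run 3175 of the 3179 called genes with both values differed in the called direction, though the calls had used these libraries. An independent reading left them out. When genes were called from male KO 1 and 2 against male WT 1 and 2 alone, 2269 of 9614 passed, and 2186 of the 2266 with both values had the same sign in the other run (96.5%, and 92.1% after centring on the median of all genes; 72.3% of all genes were higher in KO 3 than in WT 3). Against the female WT library of their own run, male KO 1 and 2 kept the called direction in 94.1% of the 3181 genes, which again had been called with these KO libraries.

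Of the 36 gene lists with at least 3 tested members, 22 passed camera with its preset correlation, 13 higher and 9 lower in KO than other genes. With an estimated correlation camera called 0 lists, with 9 under the threshold before adjustment and a lowest adjusted p of 0.116, while fry called 24. Both camera and fry called 18 lists in the same direction. Members named below to complete a count of 5 or fewer, beyond the 4 with the smallest adjusted p, were chosen after their values were seen.

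**Figure D3:**
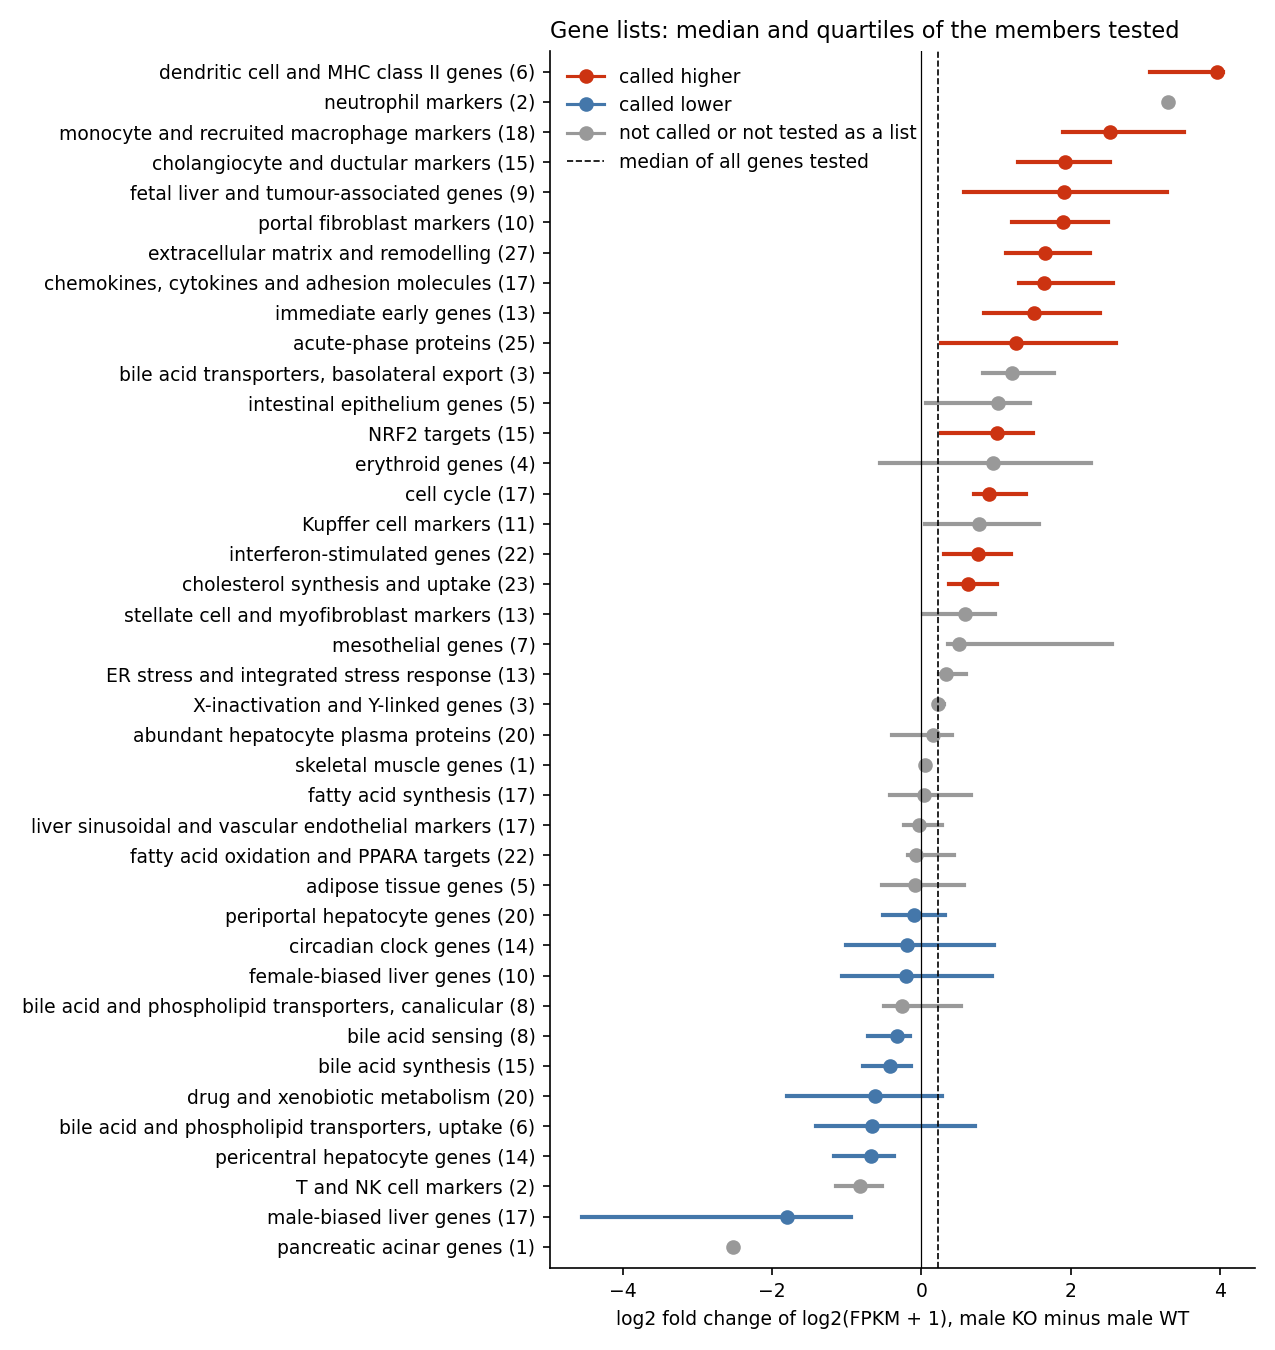
Median and quartiles (points and lines) of the log2 fold change of log2(FPKM + 1), male KO minus male WT, for 40 gene lists with tested members, whose number stands in parentheses; the dashed line is the median of all genes, 0.23. Red and blue mark lists called higher or lower by camera with its preset correlation. Dendritic cell and MHC class II genes, of which only MHC class II pathway genes were tested, have the highest median, 3.97. Among lists of at least 3 members male-biased liver genes have the lowest, −1.80.

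Several genes for making bile acids and for taking them up from blood fell in male KO, while some exporters rose. Of 15 bile acid synthesis genes tested, 7 fell, none rose and 8 did not pass; 9 fell and 1 rose when adjusted over the list alone. Rescaling in the 3 ways gave 10, 11 and 11 falls. Cyp8b1, which sets the share of cholic acid, fell from 208 ± 42.1 to 29.2 ± 21.4 FPKM (log2 change −3.26, SE 0.63, limma adjusted p = 0.00275), the sterol hydroxylase Cyp27a1 from 233 ± 22.8 to 102 ± 3.19 (−1.17, adjusted p = 1.11e-04), and Slc27a5, which activates bile acids for conjugation, from 244 to 137 (−0.84, adjusted p = 0.00194). The list median was −0.65 relative to all genes (camera adjusted p = 3.89e-08; adjusted p = 0.17 with an estimated correlation).

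Among 6 uptake transporters 3 fell, 1 rose and 2 did not pass, and 4 fell and 2 rose when adjusted over the list alone. Slc10a1, the main sodium-dependent bile acid carrier of hepatocytes, fell from 337 ± 21.3 to 112 ± 16.4 FPKM (−1.59, adjusted p = 2.87e-05) and Slco1b2, an organic anion carrier, from 222 to 118 (−0.90, adjusted p = 0.00383), beside the fall of Slco1a1 and the rise of Slc10a2. Camera called the list lower (−0.88 relative to all genes, adjusted p = 8.89e-04; adjusted p = 0.17 with an estimated correlation). The call was lost without male WT 3 (0.0605), under median-of-ratios scaling (0.076) and under quantile normalization (0.0689).

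Canalicular transporters went both ways: 2 of 8 rose, 3 fell and 3 did not pass, and 2 rose and 4 fell when adjusted over the list alone. Under quantile normalization 5 fell. The multidrug exporter genes Abcb1b (0.380 ± 0.215 to 8.45 ± 1.78 FPKM, 2.77, adjusted p = 5.23e-06) and Abcb1a (1.43, adjusted p = 0.00537) rose, and Abcg8, a subunit of the cholesterol exporter, fell from 30.7 ± 1.13 to 14.2 ± 0.987 (−1.07, adjusted p = 2.45e-04). The exporter gene Abcg2 (−0.50, adjusted p = 0.0331) and the bile salt export pump gene Abcb11 (106 to 75.1 FPKM, −0.51, adjusted p = 0.0382) also fell, but both depended on single libraries. Abcg2 was lost without male WT 2 (0.107), WT 3 (0.136), KO 1 (0.0799) or KO 2 (0.113), and Abcb11 without WT 1 (0.0939), WT 2 (0.0566), WT 3 (0.137), KO 1 (0.141) or KO 2 (0.0784). With run as a covariate, a fit that takes the difference from male KO 3 and WT 3 alone, Abcg2 differed by −0.57 and Abcb11 by −0.43, and neither passed. Nor did they with the female library pooled with male WT, where Abcg2 differed by −0.06 (adjusted p = 0.934) and Abcb11 by −0.45 (0.0571). Abcb11 was also lost without a filter (0.065) and without a trend in the prior variance (0.0581). The list was not called by camera (lower, adjusted p = 0.0603) or by fry (higher, adjusted p = 0.737), and its median was −0.26 but its mean 0.23. Camera called it lower without a filter (0.022), with the filter at FPKM 5 (0.0328) and without male WT 2 (0.0484), KO 1 (0.00554), KO 2 (0.0034) or KO 3 (6.24e-04). Without a KO library the genes that rose, Abcb1b and Abcb1a, had too few values of at least 1 FPKM and were not tested.

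For export back to blood, Ostb, a subunit of the organic solute transporter, rose from 1.57 ± 1.20 to 11.9 ± 6.43 FPKM (2.33, adjusted p = 9.44e-04) and the organic anion exporter gene Abcc5 from 0.463 to 2.46 (1.22, adjusted p = 6.86e-04). These were 2 of 3 tested, with none falling and 3 higher when adjusted over the list alone; camera gave an adjusted p = 0.0603 (0.047 without male WT 1) and fry 0.0145. Of 8 bile acid sensing genes 2 fell, 1 rose and 5 did not pass, the same counts as when adjusted over the list alone. Under the 3 rescalings none rose, and 5 fell with median-of-ratios scaling, 7 with quantile normalization and 2 without the 50 most abundant genes. Nr1i3, the nuclear receptor CAR, fell from 51.0 ± 5.80 to 21.8 ± 5.06 FPKM (−1.21, adjusted p = 5.27e-04) and Fgfr4, the hepatocyte receptor for intestinal FGF15, from 88.6 to 46.3 (−0.88, adjusted p = 0.0109; 0.0512 without male WT 3 and 0.236 with the female library pooled). Nr1i2, the nuclear receptor PXR, rose by 0.61 (adjusted p = 0.0442), a call lost under each rescaling and without male WT 1 (0.15), WT 2 (0.0858), WT 3 (0.0963) or KO 1 (0.136). It also did not pass without a filter (0.0924), without a trend in the prior variance (0.0517), with library weights (0.205), with replicate number as a block (0.0521) or with run as a covariate (0.251). The sensing list was lower than other genes (−0.56 relative to all genes, camera adjusted p = 8.89e-04; adjusted p = 0.26 with an estimated correlation), and fry did not call it (adjusted p = 0.072).

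Of 23 genes of cholesterol synthesis and uptake 15 rose, none fell and 8 did not pass, with the same counts when adjusted over the list alone. The 15 rises became 9 under median-of-ratios scaling and 11 under each of the other rescalings. Sqle, which encodes squalene epoxidase, rose by 1.64 (limma adjusted p = 3.63e-04), the squalene synthase gene Fdft1 from 13.8 to 28.1 (0.98, adjusted p = 4.39e-04), and Mvd, of the mevalonate pathway, by 1.24 (adjusted p = 0.00133). The median was 0.41 relative to all genes (camera adjusted p = 0.00738; adjusted p = 0.538 with an estimated correlation).

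Fatty acid genes were divided. Among 17 fatty acid synthesis genes 7 rose, 2 fell and 8 did not pass, and 8 rose and 4 fell when adjusted over the list alone. Beside Scd1, the fatty acid synthase Fasn (11.9 ± 1.04 to 24.2 ± 5.40 FPKM, 0.95, adjusted p = 0.0025) and the acetyl-CoA carboxylase Acaca (2.96 to 7.53, 1.08, adjusted p = 0.00277) rose. The carbohydrate-response factor Mlxipl (14.6 to 7.26, −0.93, adjusted p = 0.00182) and the carboxylase Acacb (−0.75, adjusted p = 0.0149) fell. Acacb was lost without male WT 2 (0.0638) or WT 3 (0.0598) and with the female library pooled with male WT (0.128). The list's median was 0.04 and its mean 0.42, with the median turning to −0.31, −0.17 and −0.16 under the 3 rescalings, which gave 4, 6 and 6 rises and 4 falls each. Camera placed it lower (adjusted p = 0.639) and fry higher (adjusted p = 0.0212).

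Of 22 genes of fatty acid oxidation and targets of the receptor PPARA, 4 rose, 3 fell and 15 did not pass, also when adjusted over the list alone. The fatty acid translocase Cd36 (2.64 ± 0.351 to 27.9 ± 7.07 FPKM, 2.96, adjusted p = 3.52e-06), the pantetheinase Vnn1 (2.40, adjusted p = 1.36e-05), the hormone gene Fgf21 (2.05, adjusted p = 0.00187) and Cpt1a (0.64, adjusted p = 0.0139) rose. Acot1, an acyl-CoA thioesterase (−1.59, adjusted p = 0.00132), Cpt2 (−0.60, adjusted p = 0.0121) and Cyp4a10 (−1.63, adjusted p = 0.0194) fell. Vnn1 and Fgf21 had 12.6 and 7.91 FPKM in the female WT library, and pooling it with male WT ended both calls (0.0514 and 0.121) and that of Cpt1a (0.171). Calls were lost for Cpt1a without male WT 1 (0.0593) or WT 3 (0.0534), for Cpt2 without WT 3 (0.0537) and for Cyp4a10 without WT 2 (0.0761), WT 3 (0.0706) or a filter (0.0933), and Cpt1a was lost under each rescaling. The list was not called (camera lower, adjusted p = 0.0594, median −0.07, mean 0.18; fry higher, 0.345), but was called lower without male WT 1 (0.0172) or KO 2 (0.0163), without a filter (0.0265), with the filter at FPKM 5 (0.0291), rescaled without the 50 most abundant genes (0.0326), with run as a covariate (0.0331) and with the female library pooled (0.0021). The 3 rescalings gave 3 rises each and 6, 7 and 5 falls. Without KO 2, Fgf21 did not reach the filter and was not tested.

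Of 20 genes of drug and xenobiotic metabolism 11 fell, 2 rose and 7 did not pass, and 12 fell and 3 rose when adjusted over the list alone. Cyp2c54 fell from 138 ± 27.3 to 9.35 ± 1.72 FPKM (−3.74, SE 0.19, limma adjusted p = 3.67e-07), Cyp2c50 from 260 to 33.6 (−2.96), Cyp2c37 from 58.4 to 9.21 (−2.59) and Cyp2c29 from 1331 ± 133 to 305 ± 28.1 (−2.12, adjusted p = 6.13e-06). Those that rose were Gstm1, a glutathione transferase (0.89, adjusted p = 0.00928), and the glucuronosyltransferase Ugt1a9 (0.78, adjusted p = 0.00731), neither of which passed under median-of-ratios scaling (0.0911 and 0.104). Ugt1a9 was also lost with run as a covariate (0.343). The median was −0.84 relative to all genes (camera adjusted p = 6.19e-09; adjusted p = 0.216 with an estimated correlation).

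Targets of NRF2, the transcription factor of the oxidative stress response, rose in 9 of 15 cases, with none falling and 6 not passing, also when adjusted over the list alone. Gstm3, a glutathione transferase, rose from 37.4 ± 6.21 to 337 ± 167 FPKM (3.04, adjusted p = 2.23e-05), Pgd, of the pentose phosphate pathway, from 10.4 to 34.2 (1.61) and Nqo1, a quinone reductase, from 2.15 to 9.88 (1.70). The list stood 0.78 above all genes (camera adjusted p = 0.0134; adjusted p = 0.538 with an estimated correlation). Of 13 genes of endoplasmic reticulum stress 3 rose and 10 did not pass, also when adjusted over the list alone. They were the stress-induced transcription factors Atf3 (0.324 to 12.7 FPKM, 3.05, adjusted p = 5.27e-04) and Ddit3 (5.90 to 18.4, 1.55, adjusted p = 0.00623) and the pseudokinase Trib3 (0.94, adjusted p = 0.0227). Ddit3 was lost without male WT 1 (0.0512), and Trib3 without WT 1 (0.105) or WT 2 (0.075) and under each rescaling. Trib3 was also lost without a filter (0.0839), with library weights (0.0737), with run as a covariate (0.187) and with the female library pooled with male WT (0.498). The list was not called (camera adjusted p = 0.406), and its median of 0.33 turned to −0.02 under median-of-ratios scaling.

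Markers of bile duct cells and genes of scar matrix rose almost throughout. Of 15 cholangiocyte and ductular markers tested, of 22 in the files, 14 rose and 1 did not pass, also when adjusted over the list alone. Spp1, the secreted phosphoprotein osteopontin, rose from 32.6 ± 2.14 to 453 ± 23.7 FPKM (3.76, SE 0.13, limma adjusted p = 3.95e-08), Wfdc2, an epithelial secretory protein, from 3.63 to 47.6 (3.38), the tight-junction protein gene Cldn4 from 0.124 to 5.21 (2.45) and Epcam, an epithelial adhesion molecule, from 0.654 to 7.60 (2.37). The median was 1.70 relative to all genes (camera adjusted p = 3.3e-08; adjusted p = 0.17 with an estimated correlation).

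Extracellular matrix and remodelling genes rose in 26 of 27 cases, also when adjusted over the list alone. Timp1, an inhibitor of matrix metalloproteinases, rose from 0.305 ± 0.199 to 22.1 ± 0.983 FPKM (4.16, adjusted p = 1.12e-07), Col3a1, a fibrillar collagen gene, from 6.04 ± 1.40 to 71.0 ± 11.6 (3.36, adjusted p = 8.54e-07) and Lum, the collagen-binding lumican, from 4.74 to 46.6 (3.04). Fn1, the fibronectin gene, which hepatocytes also express, had 112 and 141 FPKM and did not pass (adjusted p = 0.251), but passed without male KO 1 (0.0467) and with library weights (0.00549). The median was 1.43 relative to all genes (camera adjusted p = 1.3e-12; adjusted p = 0.294 with an estimated correlation). Portal fibroblast markers rose in 9 of 10 cases, also when adjusted over the list alone, among them Mfap4, a microfibril protein (2.61), Dpt, dermatopontin (3.14 to 26.7 FPKM, 2.75), and Entpd2, an ectonucleotidase (1.54 to 14.7, 2.59). Fbln2, a fibulin, had 0.979 and 1.60 FPKM (adjusted p = 0.217) and passed with library weights (0.00709). That list stood 1.67 above all genes (camera adjusted p = 1.92e-06; adjusted p = 0.17 with an estimated correlation).

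Stellate cell and myofibroblast markers were less uniform: 7 of 13 rose, 2 fell and 4 did not pass, and 8 rose and 2 fell when adjusted over the list alone. Under the 3 rescalings 5, 3 and 4 rose. Tagln, a smooth muscle actin-binding protein (5.07 to 15.2 FPKM, 1.41), Pdgfrb, a mesenchymal growth factor receptor (2.14 to 7.77, 1.46), and Des, desmin (2.92 to 8.07, 1.22), rose. Ecm1, an inhibitor of latent TGF-beta activation that hepatocytes also make (97.6 to 42.1, −1.20), and the neuropeptide receptor gene Vipr1 (8.41 to 3.95, −0.92) fell. Ecm1 was lost with sequencing run as a covariate (0.0603). Camera did not call the list (adjusted p = 0.569), while fry placed it higher (adjusted p = 0.0145).

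All 18 monocyte and recruited macrophage markers tested rose, also when adjusted over the list alone, including the lysozyme gene Lyz2 from 25.7 ± 4.41 to 453 ± 15.4 FPKM (4.10, SE 0.15, limma adjusted p = 3.95e-08), Trem2, a lipid-sensing receptor, by 3.90, and Cd14, the lipopolysaccharide co-receptor, from 1.30 to 48.9 (4.40). That list stood 2.30 above all genes (camera adjusted p = 2.62e-15; adjusted p = 0.17 with an estimated correlation). All 6 dendritic cell and MHC class II genes tested, of 14, rose, also when adjusted over the list alone: Cd74, the invariant chain, went from 21.9 ± 1.79 to 377 ± 47.8 FPKM (4.04, adjusted p = 3.95e-08), H2-Aa from 4.84 to 97.1 (4.09) and H2-Ab1 from 3.22 to 67.8 (4.03). These 6 were all genes of the MHC class II pathway, and no other member was tested. The list thus does not speak for dendritic cells as such. The list's median was 3.74 relative to all genes (camera adjusted p = 6.19e-09, and adjusted p = 0.116 with an estimated correlation).

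Kupffer cell markers, those of resident liver macrophages, rose in 6 of 11 cases, with none falling and 5 not passing, also when adjusted over the list alone. The complement genes C1qb (26.0 to 115 FPKM, 2.11), C1qa (37.3 to 139, 1.88) and C1qc (27.7 to 114) and the macrophage marker Emr1 (1.42 to 4.95, 1.28) were among those that rose. The 5 that did not pass were Clec4f, a lectin of Kupffer cells (difference −0.24), Timd4 (−0.09; lower under quantile normalization, adjusted p = 0.04), Vsig4 (0.13), Folr2 (0.17) and Slc40a1 (−0.03). Camera did not call the list (adjusted p = 0.0594), but did without male WT 1 (0.0138), KO 1 (0.0156) or KO 2 (0.0262) and with run as a covariate (0.00601). Without KO 1 or KO 2, Fabp7, which rose, did not reach the filter. Fry placed the list higher (adjusted p = 0.00932). Of 17 chemokine, cytokine and adhesion genes 15 rose, none fell and 2 did not pass, and 16 rose when adjusted over the list alone. Cxcl14 rose from 0.156 to 24.7 FPKM (4.44), the monocyte attractant Ccl2 from 0.349 ± 0.312 to 24.2 ± 16.8 (4.04), Ccl5 from 0.160 to 6.60 (2.72) and Cxcl16 from 2.75 to 21.4 (2.57). The median was 1.43 relative to all genes (camera adjusted p = 2.54e-08; adjusted p = 0.17 with an estimated correlation).

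Other leukocyte lists were measured poorly. Of 14 neutrophil markers in the files 2 were tested and both rose, also when adjusted over the list alone: S100a8 (0.898 to 15.9 FPKM, 3.33) and S100a9 (0.987 to 20.3, 3.26), subunits of calprotectin. Of 26 T and NK cell markers only Zap70, a T cell kinase (15.6 ± 2.72 and 6.85 ± 6.31 FPKM, adjusted p = 0.0549), and the transcription factor gene Tcf7 (2.78 and 2.29) were tested, and neither passed. Zap70 passed as lower when adjusted over the list alone, and over all genes without male KO 1 (7.09e-05) or KO 3 (0.0498), with library weights (1.19e-04), replicate number as a block (0.034), run as a covariate (1.04e-04) or the female library pooled with male WT (0.0363). Tcf7 passed as lower under median-of-ratios scaling (0.0318) and quantile normalization (0.00725). None of 11 B and plasma cell markers passed the filter. Interferon-stimulated genes rose in 12 of 22 cases, with none falling and 10 not passing, and in 13 when adjusted over the list alone. Oas1a (0.844 to 5.68 FPKM, 1.86), an antiviral synthetase, Usp18 (2.27 to 8.19, 1.51), a negative regulator of the response, and the transcription factor gene Irf7 (7.59 to 20.4, 1.32) rose. The list stood 0.54 above all genes (camera adjusted p = 0.00461; adjusted p = 0.275 with an estimated correlation), a call lost with sequencing run as a covariate (0.13).

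Acute-phase genes, which hepatocytes express in inflammation, mostly rose: 16 of 25 rose, 2 fell and 7 did not pass, and 17 rose and 2 fell when adjusted over the list alone. Beside Lcn2, the orosomucoid gene Orm2 rose from 9.41 ± 0.783 to 300.4 ± 110.0 FPKM (4.79, limma adjusted p = 3.73e-07) and haptoglobin, Hp, from 1310 ± 92.4 to 8094 ± 139 (2.63, adjusted p = 4.41e-06). Saa4, a constitutive serum amyloid (141 to 57.3, −1.33), and the protease inhibitor gene Serpina3m (979 to 402, −1.33) fell. The median was 1.04 relative to all genes (camera adjusted p = 5.77e-04; adjusted p = 0.216 with an estimated correlation). Abundant hepatocyte plasma protein genes went both ways: 4 of 20 rose, 1 fell and 15 did not pass, and 3 rose and 1 fell when adjusted over the list alone. Under the 3 rescalings 1, 5 and 2 rose and 3, 3 and 4 fell. Trf, transferrin, rose from 5926 ± 531 to 14610 ± 3142 FPKM (1.28, adjusted p = 0.00298), and Ambp (0.77), Ahsg (0.69) and Gc (0.60) rose by less. Serpina1a, alpha-1-antitrypsin, fell from 2210 to 840 (−1.45, adjusted p = 0.00503), but it shares reads with its paralogs and had no estimate in male WT 3, and with failed estimates at 0 its difference was 2.25 (adjusted p = 0.522).

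The smaller rises of plasma protein genes depended on single libraries and on scaling. Ambp was lost without male WT 3 (0.0504) or KO 2 (0.0574), Ahsg without WT 1 (0.134), WT 2 (0.0533), WT 3 (0.111) or KO 2 (0.135), and Gc without WT 1 (0.144), WT 2 (0.086), WT 3 (0.0924), KO 2 (0.158) or KO 3 (0.0583), and all 3 under median-of-ratios scaling. With run as a covariate none of the 3 passed (0.229, 0.173 and 0.329). Ahsg and Gc were also lost without the 50 most abundant genes (0.0642 and 0.086), without a filter (0.0994 and 0.0917), with replicate number as a block (0.0961 and 0.109) and with the female library pooled with male WT (0.393 and 0.125), and Gc with failed estimates at 0 (0.0521). The list's median of 0.15 turned to −0.22 under that scaling and −0.06 without the 50 most abundant genes, its mean was 0.01, and neither camera (lower, adjusted p = 0.498) nor fry (higher, adjusted p = 0.133) called it.

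Cell cycle genes rose in 14 of 17 cases, with none falling and 3 not passing, and in 15 when adjusted over the list alone. Ccnd1, cyclin D1, rose from 2.68 ± 0.666 to 29.1 ± 18.4 FPKM (2.88, adjusted p = 1.25e-04), and the S-phase and mitosis genes Mcm6 (0.368 to 2.67, 1.40), Cdk1 (0.217 to 1.82, 1.19) and Ccne1 (1.08) rose from low levels. The median was 0.68 relative to all genes (camera adjusted p = 1.14e-04; adjusted p = 0.44 with an estimated correlation), a call lost with the filter at FPKM 5 (0.0845). Of 9 fetal liver and tumour-associated genes 6 rose, 1 fell and 2 did not pass, also when adjusted over the list alone. Beside Ly6d, the galectin gene Lgals1 (8.36 to 162 FPKM, 4.13), the trefoil factor gene Tff3 (0.145 to 11.1, 3.29) and Cd24a, a surface glycoprotein (0.684 to 11.6, 2.85), rose, and Glul, glutamine synthetase of pericentral hepatocytes (175 to 95.4, −0.86), fell. The list stood 1.68 above all genes (camera adjusted p = 0.00579, and adjusted p = 0.196 with an estimated correlation). The call was lost without male KO 1 (0.0585), KO 2 (0.417) or KO 3 (0.26). In these fits Ly6d and Tff3 did not reach the filter and were not tested.

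Of 14 pericentral genes, those of hepatocytes near the central vein, 6 fell in KO, none rose and 8 did not pass, and 7 fell when adjusted over the list alone. The 3 rescalings gave 9, 11 and 9 falls. The cytochrome P450 genes Cyp2e1 (3617 ± 604 to 1035 ± 274 FPKM, −1.82, adjusted p = 1.75e-04) and Cyp1a2 (645 ± 127 to 187 ± 48.4, −1.79, adjusted p = 1.25e-04) and the glutamate transporter gene Slc1a2 (26.2 to 7.71, −1.71) fell. The median was −0.90 relative to all genes (camera adjusted p = 8.03e-09; adjusted p = 0.17 with an estimated correlation). Periportal genes, those of hepatocytes near the portal tract, went both ways: 5 of 20 rose, 3 fell and 12 did not pass, and 5 rose and 4 fell when adjusted over the list alone. Under the 3 rescalings 5 rose each time, and 6, 6 and 7 fell. Hsd17b13, a lipid droplet protein (143 ± 16.9 to 500 ± 86.6 FPKM, 1.79), Cdh1, E-cadherin (6.39 to 23.7, 1.69), Aldh1b1, an aldehyde dehydrogenase (1.15), Sox9, a biliary transcription factor (1.24), and Ctsc, a cathepsin (0.86), rose. Cyp2f2, a cytochrome P450 (1056 to 278, −2.11), G6pc, the last enzyme of gluconeogenesis (179 to 30.2, −2.94), and Hal, a histidine-degrading enzyme (−1.22), fell. Camera called the list lower (−0.33 relative to all genes, adjusted p = 0.0175; adjusted p = 0.339 with an estimated correlation), while fry placed it higher (adjusted p = 0.749). The call was lost under median-of-ratios scaling (0.27), quantile normalization (0.449) and without male KO 3 (0.154). Sox9 was lost without WT 1 (0.0602) and Ctsc with run as a covariate (0.0597).

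Of 17 endothelial markers 2 rose, 1 fell and 14 did not pass, and 1 rose and none fell when adjusted over the list alone. The balance depended on scaling, with 1 rise and 4 falls under median-of-ratios scaling, 1 and 6 under quantile normalization and 1 and 1 without the 50 most abundant genes. The Fc receptor gene Fcgr2b rose by 0.77 (SE 0.16, adjusted p = 0.00452). The scavenger receptor gene Stab1 rose (0.59, adjusted p = 0.0368) and the phosphatase gene Ptprb fell (−0.54, adjusted p = 0.0381), but both calls depended on single libraries. Stab1 was lost without male WT 2 (0.0912), WT 3 (0.141), KO 2 (0.0583) or KO 3 (0.0747) and under each rescaling, and Ptprb without WT 1 (0.136), WT 2 (0.0725), WT 3 (0.0679), KO 1 (0.0731) or KO 2 (0.178). Both were lost without a filter (0.0579 and 0.0675), and Ptprb with run as a covariate (0.476) and with the female library pooled with male WT (0.123). The list was not called by camera (lower, adjusted p = 0.0594, median −0.03, mean 0.03) or by fry (higher, adjusted p = 0.898). Camera called it lower without WT 2 (0.0233), WT 3 (0.014) or a filter (0.0355), with library weights (0.0218) and with the female library pooled with male WT (0.0459).

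Most genes tested that are normally higher in the male mouse liver fell in male KO. Of 17 male-biased genes tested, 14 fell, 1 rose and 2 did not pass, also when adjusted over the list alone. Hsd3b5, Slco1a1, Mup21 and Cyp7b1 led the list, whose median was −2.03 relative to all genes (camera adjusted p = 1.05e-19; adjusted p = 0.17 with an estimated correlation). Mup20, a male pheromone protein, was the exception: it rose by 1.59 (adjusted p = 0.0465), with 7632, 3922 and 1101 FPKM in the KO libraries and 1074 ± 187 in male WT. That call was lost under each rescaling and without WT 1 (0.18), WT 2 (0.109), WT 3 (0.0779), KO 1 (0.053) or KO 2 (0.0801). It was lost without a filter (0.16), with replicate number as a block (0.0633) and with the female library, at 52.6 FPKM, pooled with male WT (0.0734). It was also lost with a pseudocount of 3 (0.0501), with the filter at FPKM 5 (0.0541), without a trend in the prior variance (0.0504) and with failed estimates at 0 (0.0502). With run as a covariate it turned to −0.23, because that fit takes the difference from male KO 3 and WT 3 alone, and Mup20 was higher in WT 3 (1290 FPKM).

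Female-biased liver genes did not rise as a group in male KO. Of 10 tested, 4 rose, 4 fell and 2 did not pass, and 4 rose and 5 fell when adjusted over the list alone. Under the 3 rescalings 2, 1 and 2 rose and 5 fell each time. The cytochrome P450 genes Cyp2b10 (15.7 to 3.77 FPKM, −1.76), Cyp2b9 (1.90 to 0.358, −1.08), Cyp3a44 (2.54 to 0.695, −1.04) and Cyp4a10 fell. Those that rose were Abcd2, a peroxisomal transporter (0.448 to 3.30, 1.49), Cyp2a4, a steroid hydroxylase (1.04 to 9.10, 1.99), Fmo2, a monooxygenase (0.97), and the transcription regulator Trim24 (0.85). Cyp2a4 was lost under quantile normalization (0.0622), without a filter (0.0539) and with run as a covariate (difference 0.87, adjusted p = 0.245). Pooling the female library with male WT ended the calls of Cyp2a4 (0.936), Cyp2b9 (0.148), Abcd2 (0.153), Cyp3a44 (0.167), Fmo2 (0.217) and Trim24 (0.334). Each of these had a higher value in the female library than in any male WT library, such as 274 FPKM for Cyp2a4 and 281 for Cyp3a44. Pooling thus widens the WT group for these genes and does not weigh the change between the male groups. Fmo2 was lost without WT 1 (0.147), WT 2 (0.0631) or WT 3 (0.0619), and Trim24 without WT 1 (0.131), WT 2 (0.137), WT 3 (0.0561) or KO 3 (0.0687), and both under each rescaling and without a filter (0.101 and 0.119). Trim24 was also lost with library weights (0.217). Camera placed the list lower (−0.43 relative to all genes, adjusted p = 0.038, and adjusted p = 0.349 with an estimated correlation). That call was lost under each rescaling (0.44, 0.426 and 0.153) and without WT 1 (0.246), WT 2 (0.44), WT 3 (0.283) or KO 3 (0.0593). It was also lost with run as a covariate (0.0797) and with all 7 libraries in the fit (0.083), and fry did not call the list (adjusted p = 0.439). The Y-linked genes Eif2s3y (difference 0.38; adjusted p = 0.0225 with run as a covariate), Ddx3y (0.14) and Uty (0.22) did not pass between male WT and KO, also when adjusted over the list alone, and camera did not call them (lower, adjusted p = 0.865; fry higher, 0.551). Their median of 0.22 turned to −0.04 and −0.17 under median-of-ratios and quantile scaling.

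Several core clock genes differed between the groups and among the KO libraries. Of 14 tested, 3 rose, 5 fell and 6 did not pass, and 3 rose and 6 fell when adjusted over the list alone. Under quantile normalization 1 rose and 7 fell. The output and repressor genes Dbp (3.84, adjusted p = 0.0121), Nr1d1 (2.07, adjusted p = 0.00457) and Nr1d2 (1.48, adjusted p = 0.014) rose, and Cry1 (−1.24), Npas2 (−1.30), Nfil3 (−1.14) and Arntl (−1.47) were among those that fell. Dbp had 67.7, 1.23 and 40.3 FPKM in male KO 1, 2 and 3, at most 0.493 in male WT and 37.5 in the female WT library. Arntl had 0.973, 5.84 and 1.39 in KO, 6.51 to 9.33 in male WT and 1.52 in the female library. Pooling the female library with male WT ended the calls of Dbp (0.179), Nr1d1 (0.272), Nr1d2 (0.0927), Arntl (0.172), Npas2 (0.136), Nfil3 (0.165) and Cry1 (0.0533). Dbp was also lost without WT 1 (0.0813) or under quantile normalization (0.0547), Nr1d2 likewise (0.0856 and 0.0693), and Arntl without WT 1 (0.057) or WT 3 (0.0546). Without a filter the calls of Dbp (0.0782), Nr1d2 (0.0741), Arntl (0.0765) and Nfil3 (0.0635) were lost. With library weights the differences were 0.81 for Dbp, 0.35 for Nr1d2, −0.43 for Arntl and −0.39 for Nfil3, and none of these passed. Camera called the list lower (−0.43 relative to all genes, adjusted p = 0.0116, and adjusted p = 0.26 with an estimated correlation), though its mean was 0.19. The call was lost under each rescaling (0.223, 0.227 and 0.093) and with the filter at FPKM 5 (0.0934), and fry did not call the list (adjusted p = 0.353). The hour of sampling was not given in the sources used here.

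**Figure D4:**
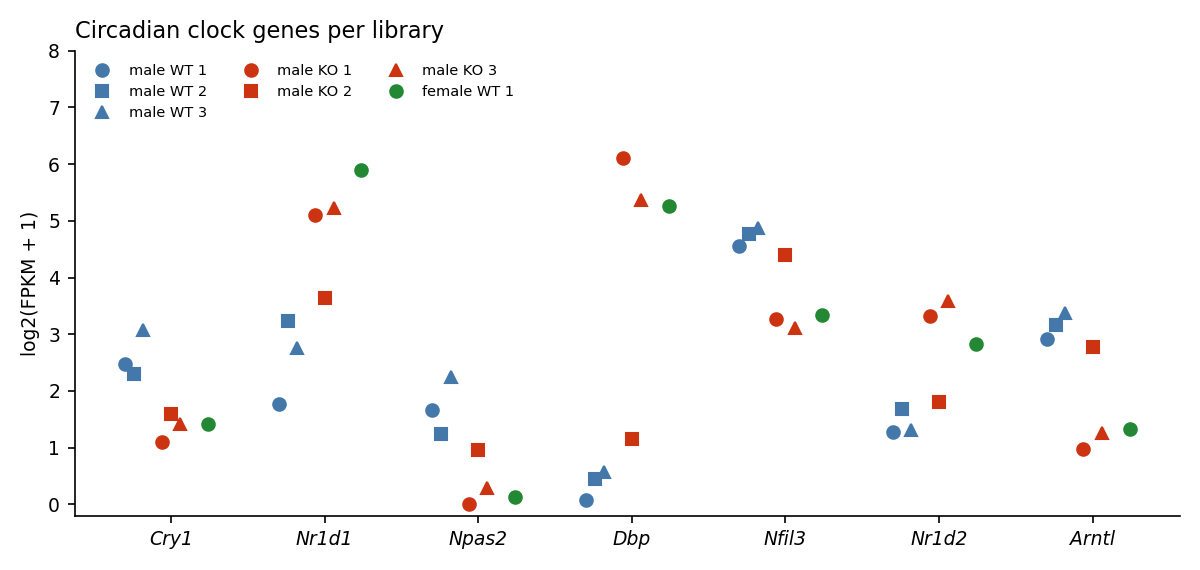
Level, as log2(FPKM + 1), of the 7 circadian clock genes with the smallest adjusted p between male KO and male WT, 1 point per library. Male KO 1, male KO 3 and the female WT library lie together at high Dbp (67.7, 40.3 and 37.5 FPKM) and low Arntl (0.973, 1.39 and 1.52), while male KO 2 has 1.23 and 5.84 FPKM.

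Immediate early genes rose in 9 of 13 cases, with none falling and 4 not passing, and in 10 when adjusted over the list alone. Junb, a subunit of AP-1, rose from 3.11 ± 1.61 to 28.9 ± 7.70 FPKM (2.91, adjusted p = 5.02e-05), Egr1, a growth-factor-induced transcription factor, from 0.276 to 6.50 (2.39) and Btg2, an antiproliferative gene, from 1.04 to 9.36 (2.27). The list stood 1.29 above all genes (camera adjusted p = 0.00569, and adjusted p = 0.538 with an estimated correlation). The call was lost without male KO 3 (0.0593), where Egr1 did not reach the filter, and with the filter at FPKM 5 (0.0697).

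Markers of blood and of tissues near the liver were mostly too low to test. Of 4 erythroid genes Alas2, the first enzyme of erythroid heme synthesis, fell (115 to 53.4 FPKM, −1.35, adjusted p = 0.0375), the same count as when adjusted over the list alone, but not without WT 1 (0.101), WT 2 (0.0989), WT 3 (0.0979) or a filter (0.138), under median-of-ratios scaling (0.0521) or with the female library pooled with male WT (0.567). The alpha-globin gene Hba-a2 had 1044, 14.3 and 17.2 FPKM in the KO libraries and 1.33, 14.8 and 42.2 in male WT. The erythroid list was not called (camera lower, adjusted p = 0.196, though its median was 0.96 and mean 0.77), but was called lower without KO 1 (0.0325), with library weights (0.0362) and with run as a covariate (0.00697). Under quantile normalization and without the 50 most abundant genes 2 of its genes fell. The only pancreatic acinar gene tested of 19, the elastase gene Cela1, fell from 58.5 ± 3.57 to 9.56 ± 3.02 FPKM (−2.53, adjusted p = 1.01e-05), also when adjusted over the list alone. Of 5 adipose genes 2 rose, 1 fell and 2 did not pass, also when adjusted over the list alone. The lipid droplet gene Cidec rose (0.612 to 6.29, 2.17), as did Fabp4, a fatty acid carrier (0.57, lost without WT 3 at 0.0691 or KO 2 at 0.0714, with run as a covariate at 0.102 and under each rescaling). The carbonic anhydrase gene Car3 fell (3157 to 992, −1.83). The adipose list was not called (camera lower, adjusted p = 0.602, median −0.08, mean 0.06; fry higher, 0.123).

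Of 5 intestinal epithelium genes 3 rose, 1 fell and 1 did not pass, also when adjusted over the list alone. Apoa4, an apolipoprotein of the gut and the fatty liver (106 to 292 FPKM, 1.45), Tff3 and the glucose carrier gene Slc5a1 (0.238 to 1.56, 1.02) rose, Fabp2, a fatty acid carrier, fell (−0.89; adjusted p = 0.0511 without WT 2 and 0.0544 without a filter), and Anpep, an aminopeptidase, had 32.6 and 33.9 FPKM. Camera did not call the list (adjusted p = 0.333) and fry placed it higher (adjusted p = 0.00409). Of 7 mesothelial genes 3 rose and 4 did not pass, also when adjusted over the list alone. The keratin genes Krt8 (126 to 880 FPKM, 2.77) and Krt18 (137 to 717, 2.35), which hepatocytes and bile duct cells also express, and Slpi, a secreted protease inhibitor (4.15), rose. Camera gave an adjusted p = 0.0594 for that list, but called it higher without WT 1 (0.0429), WT 2 (0.0362), KO 1 (1.98e-05), KO 2 (0.0193) or KO 3 (0.00942), as did fry (0.0212). The only skeletal muscle gene tested, Mylpf, had 0.931 and 0.992 FPKM and did not pass (adjusted p = 0.857), also when adjusted over the list alone, and none of the 13 mitochondrially encoded genes was found under its symbol in the files.

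The second comparison set the female WT library against the 3 male WT libraries. Known sex-biased liver genes were among those that differed. The female library had 4.07 FPKM of Mup21 against 744 ± 281 (SD, n = 3) in male WT (log2 difference −7.14, SE 0.78, limma adjusted p = 0.00127) and 7.68 of Elovl3 against 563 ± 120 (−6.00, adjusted p = 0.00403). Cyp4a12a, a male-specific fatty acid hydroxylase, had 1.37 FPKM against 145 ± 23.3 (−5.94, adjusted p = 0.0118) and Mup20 52.6 against 1074 ± 187 (−4.31, adjusted p = 0.0242). Cyp2a4 was higher in the female library, with 274 FPKM against 1.04 ± 0.340 (7.09, adjusted p = 3.85e-04). Of 17 male-biased genes tested 11 were lower and none higher, and of 11 female-biased genes 8 were higher and none lower.

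Below the expression filter in males, and so not tested, Cyp2c40 had 141 FPKM in the female library against 0.179 in male WT, the sulfotransferase gene Sult2a1 110 against 0.0196 and Cyp2c69 168, an estimate with the status FAIL, against 0.824. The Y-linked genes Eif2s3y (adjusted p = 0.00118), Ddx3y (5.15 FPKM in male WT, adjusted p = 0.0075), Uty (1.51, adjusted p = 0.0839) and Kdm5d (0.951, not tested) were listed at 0 in the female library. Xist, the RNA of X inactivation, had 1.17 FPKM there and 0.0144 in male WT. Without male WT 1 the calls of Elovl3 (0.0543), Cyp4a12a (0.0949), Mup20 (0.132) and Ddx3y (0.0527) were lost, as was that of Mup20 without WT 2 (0.0574) or WT 3 (0.0779).

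**Figure D5:**
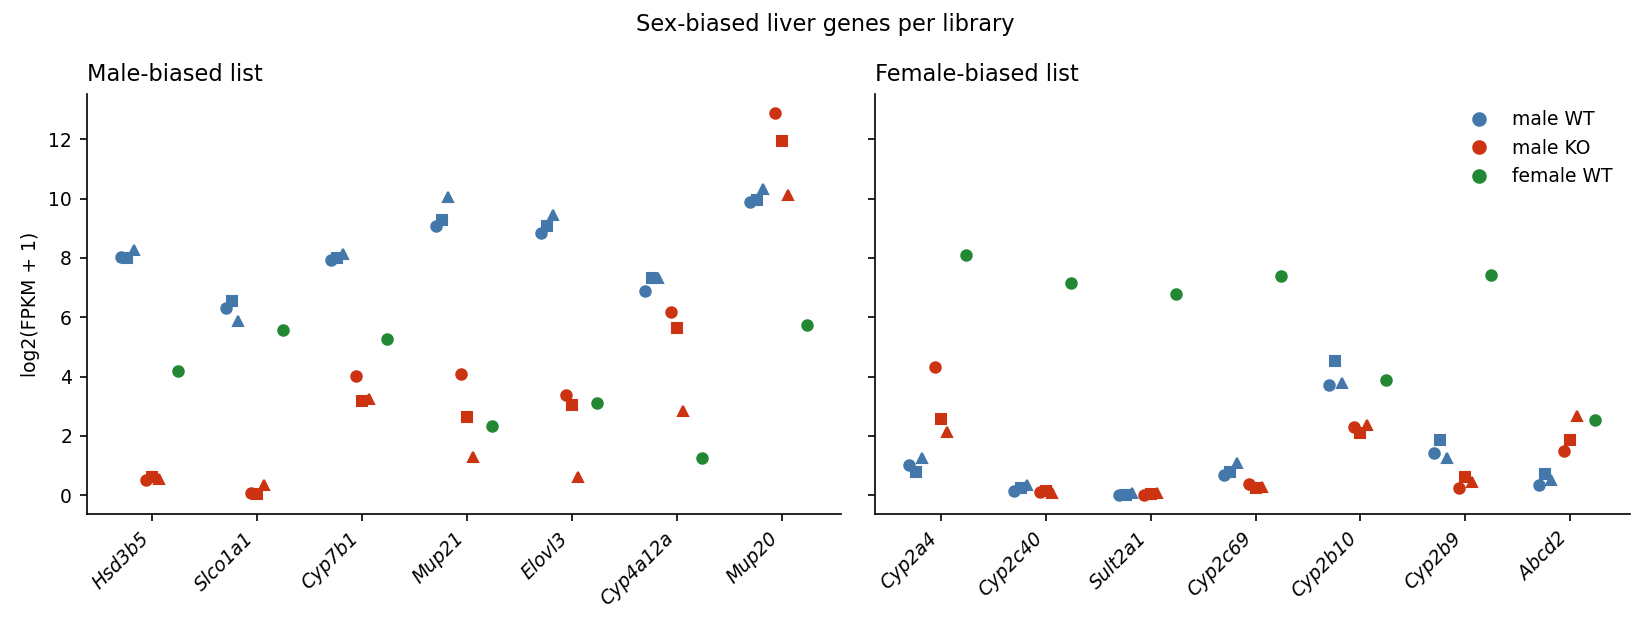
Level, as log2(FPKM + 1), of 7 male-biased (left) and 7 female-biased (right) liver genes in each library; circles, squares and triangles are replicates 1, 2 and 3. In male KO, Hsd3b5 (0.470 FPKM) lies below the female WT library (17.1), while Sult2a1 and Cyp2c40 remain near 0 in both male groups against 110 and 141 FPKM in the female library.

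Over 10702 genes, 118 passed between the female and the male WT libraries, 39 higher and 79 lower in the female. The count was 40 without male WT 1, 70 without WT 2 and 58 without WT 3, and the median difference of all genes was −0.12. Median-of-ratios scaling gave 132 genes higher and 81 lower, and quantile normalization 72 and 75. With run as a covariate 231 genes passed. With a single female library, sex cannot be separated from differences between animals. Its run held no male WT library, so sex and run could not be compared directly. The fit with run as a covariate links them only through male KO 3 and WT 3. The filter asked for 3 libraries, so a gene expressed only in the female library was not tested, which lowers the number called higher. Without a filter, more of the genes that passed were higher than lower in the female library.

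The changes in male KO were then set beside the female difference. Of 79 genes lower in the female library 38 also fell in male KO, 10 rose and 31 did not pass, and of 37 genes higher in the female and tested in both 20 rose, 6 fell and 11 did not pass. Independent lists of these sizes among 10650 genes would share 3.52 lower and 9.40 higher genes. By the same reckoning 20.07 genes would be lower in the female and higher in KO and 1.65 the reverse. The 50 simulations of unchanged groups against the same male WT libraries shared none, but those simulations called almost no genes, so that this count is no test of the shared controls. Across genes, which are not independent replicates, the correlation of the log2 differences was 0.336 against a simulated mean of 0.358, and the covariance 0.128 against 0.0311. Both comparisons use the same 3 male WT libraries, too few to split, so part of the excess may come from the shared controls. The female library also shared its sequencing run with some of the male KO libraries and with no male WT library. A difference between runs could thus move both comparisons the same way, and its part in the excess was not tested.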

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

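The tests described in this part were chosen after the results they weigh had been seen. A signal stood in data outside the comparisons: in male KO 2 and male KO 3 the deposited files give an estimate for 15 and 15 entries of Mup genes, with FPKM sums of 33.3 and 10.4, whereas in the other 5 libraries these entries hold failed estimates. They were missing from every comparison, and the difference was not tested.

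Many genes changed between male KO and male WT, and the libraries were spread over 3 sequencing runs. Genes called in the 2 runs with a single male genotype each kept their sign in 92.1% of cases in the run that held both, after centring. With run as a covariate 2681 genes passed (2246 higher and 435 lower), of which 2211 were among the 3181. Of the 3181, 3177 kept their sign, but that fit takes the difference between the genotypes from male KO 3 and WT 3 alone. The calls had used these libraries, so this count is no separate support. By the 92.1% from the calls that left these libraries out, a run effect might account for some genes but could not be the whole cause. Among the 10 ways to part the 6 male libraries into 3 and 3, 1 gave as many genes as the real grouping, which was the real grouping itself, with 3181 genes against 2 in the highest other. For gene lists by camera with its preset correlation, 2 groupings gave as many: the real one gave 22 lists and the others 4 to 24, while fry gave 24 and 0. These are too few splits for a share under 0.05, and the loss of Mdr2 as an explanation of the changes stays open as not tested against other differences between the animals.

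Most changed genes were higher in KO. After median-of-ratios scaling 54.2% of changed genes were higher against 85.1% as deposited, but that scaling brings the median gene close to 0 and so sets this share itself. By at least 1 log2, 787 genes were higher and 338 lower after it, 680 and 329 under quantile normalization and 936 and 253 without the 50 most abundant genes. Lack of scaling between libraries as an explanation of the excess stays open. Whether KO livers held more RNA of most genes was not tested.

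Most male-biased liver genes fell in male KO. A library from a female mouse labelled as male could not account for this, since the lowest FPKM of Ddx3y and Eif2s3y in a KO library was 3.93. A lower share of hepatocyte RNA could not be the whole cause either: the median change of abundant hepatocyte plasma protein genes was 0.15 against −1.80 for the male-biased genes. A full shift to the female pattern was not seen, since over the 19 female-biased genes at least 5 times higher in the female library the KO mean was at the median 1.46% of the female level; Abcd2 (69.2%) and, with smaller sex differences, Trim24 (72.4%) and Fmo2 (89.5%) came nearer to it. An effect of genotype on part of sex-biased expression stays open as untested.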

How the results depend on the processing

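The alternative with failed estimates at 0 as deposited was chosen after the data were seen. Between male KO and male WT, a filter at FPKM 5 gave 2037 genes from fewer tested, library weights gave 5700, and leaving out 1 library gave 1853 to 2769 from fewer libraries; the cause of the rise with weights was not tested. The share of changed genes that were higher was 54.2% under median-of-ratios scaling, 47.2% under quantile normalization and 69.5% without the 50 most abundant genes. Camera with an estimated correlation called 0 lists, against 9 before adjustment and 24 by fry. Fatty acid synthesis turned from lower to higher by fry (adjusted p = 0.0212), as did periportal genes (0.749). Serpina1a turned to 2.25 with failed estimates at 0, which replaces its missing value in male WT 3, and Mup20 to −0.23 with run as a covariate. The fit with run takes the difference from male KO 3 and WT 3 alone, where Mup20 had 1101 and 1290 FPKM. With replicate number as a block 3447 genes passed, but residuals of libraries with the same number correlated by −0.027, 0.012 and 0.115, so the libraries were not treated as paired. Between the female and male WT libraries 213 genes passed under median-of-ratios scaling, 231 with run as a covariate and 40 to 70 with 1 male library left out.

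Of 192 named genes with a value 167 passed, 125 of them under every alternative in which they were tested. Genes near 0 in male WT, such as Ly6d, were not tested without a KO library. Over the named genes and the alternatives that tested them, 3840 values kept direction and side of the threshold, 184 no longer passed, 41 newly passed and 2 reversed. For gene lists these counts were 760, 51, 46 and 2. For 31 sex-biased and sex-linked genes in the female comparison they were 283, 40, 9 and 0. The unknown depth limits what can be said of genes with low FPKM.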

Other observations

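The values in this part were chosen after they had been seen, and no explanation of them was tested. Blood and surface markers varied among the male KO livers. Relative to the male WT mean, the median log2 level of erythroid genes was 2.92 in male KO 1, −0.18 in male KO 2 and 0.12 in male KO 3. Hba-a2, an alpha-globin gene, had 1044 FPKM in male KO 1 and 1.33 to 54.4 in the other libraries. Mesothelial genes stood at −0.69 in male KO 1, 1.71 in male KO 2 and 1.15 in male KO 3, and at −0.56 in the female WT library.

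Other groups also ran unevenly. In male KO 1, 2 and 3 the 2 neutrophil genes stood at 4.30, 2.97 and 2.61. Male-biased genes were at −1.01, −1.56 and −2.75 in the same order, and at −2.97 in the female WT library. In 43 of the genes called between male KO and male WT, male WT 3 and the female WT library both lay nearer to the KO mean than to the mean of male WT 1 and 2, which shared a run.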
